A study of Mus musculus with 3 samples.

How the data were processed

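Strand-specific libraries of polyadenylated RNA from mouse brain, liver and testis, 1 per tissue, were sequenced as 76-cycle single-end reads in 3 lanes each, per the labels' protocols, which give a mean of about 114 M reads per sample. The protocols also give a total of about 900 M reads, so that mean covers more samples than those used here. The submitters' processing notes name TopHat 1.4.0, Bowtie 0.12.5, Cufflinks 2.0.0 and the mm9 genome build. The gene annotation and the filters behind the tables are not given in the sources used here. Each deposited table gave FPKM per gene, that is fragments per kilobase of transcript and per M mapped fragments, with a lower and an upper confidence bound and an estimate status, per the file headers. The headers name no level for these bounds, which were taken as 95% bounds. The tables held 36824 rows for brain, 36823 for liver and 36824 for testis, and 305, 327 and 390 estimates were marked as failed. Failed estimates were kept at their listed values in counts of genes, and an alternative left out all estimates not marked OK. An exact 0 can be a failed estimate, so a gene at 0 is said to be listed at 0 and no fold is given for it as a single gene. List medians include such genes through the pseudocount.

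The 36809 gene identifiers present in all 3 tables were used. For 12 identifiers at more than 1 locus the FPKM values were summed. GENCODE M21, which is on another build, was used by identifier only, for symbols and gene classes. A symbol was found for 31837 identifiers, and 4972 had no match and formed a class of their own. Coordinates are those of the tables, on mm9, with 1 added to the start, since 37 of 37 mitochondrial genes then had the reference coordinates. Feature length is the span of the locus.

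The tables hold no counts, and depth was read from the intervals: the square of 2 times FPKM over its upper half-width gives implied fragments. Of the low values, 78.6% in brain, 78.9% in liver and 80.0% in testis were whole numbers within 0.1. Implied fragments came to 31.8, 86.3 and 40.9 M, and were used for depth and for thinning only. They fall short of the library sizes that FPKM and transcript length give, 65.5, 140 and 67.3 M, and of the mean read number in the labels. Their sums for testis and brain differ more than the relative depth of 1.03, so thinning removed more from testis than depth alone asks. The FPKM sums were 14084700 in brain, 1330740 in liver and 2043320 in testis. Features under 200 bp took most of the brain sum, so FPKM was used as deposited without scaling to the sum.

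Tissues were compared by size on log2(FPKM + 1), which understates the difference of low genes. A gene was called higher or lower when it differed by at least 4-fold on that scale and the authors' intervals did not overlap. With 1 library per tissue these differences have no replicate check and no test was run. Detection meant 1 FPKM or more. Restricted genes had 5 FPKM or more in a tissue and under 0.5 in both others. Shares carry exact 95% binomial intervals, which cover counting error only. Concentration was the share of FPKM in the 10 and 100 most abundant genes and the Shannon entropy of FPKM shares. Chromosome X was compared with autosomes by the median FPKM of detected genes.

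There were 29 gene lists with 473 entries, fixed before the data were examined, of which 458 matched by symbol, 6 by an older symbol and 9 not at all. Some genes are on more than 1 list. For each list the median difference was ranked among 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these libraries. The lists describe whole organs and no cells were named from them. The 11 retrogene pairs were fixed at the same time.

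Named genes followed a rule fixed before the data were examined. For each pair of tissues it took the 5 largest differences in each direction among genes at 10 FPKM or more in the higher tissue, with a symbol and no failed estimate. It also took the 3 highest members of each list in its home tissue with members 4-fold against it, the 5 most abundant genes and the 5 highest restricted genes of each library, all retrogene pairs and the Y-linked genes. Some genes that the rule gave are not reported here. Very short features filled much of that choice, and the same rule among protein-coding genes only was added after the values were seen. Chosen after seeing values were also a few other list members named for their level, the genes and families that open the other observations, the removal of features under 200 bp and scaling to the protein-coding FPKM sum.

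Alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, scaling to the FPKM sum, to the median ratio or to the sum without the 100 most abundant genes, other FPKM and fold minimums, protein-coding genes only, estimates marked OK only, size of difference without the intervals, a filter at 1 FPKM in any library and, for restriction, a tau of at least 0.9. The sum without the 100 most abundant genes leaves out of every library the 100 most abundant genes of each of the 3 libraries. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The calls were tested on simulated data in which 200 genes were changed by a known fold. The simulation used genes at 1 FPKM or more in both libraries and counting error only. Genes near 0 in 1 of the libraries were not covered. At 8-fold and 16-fold 100% of the changed genes were called in each comparison. In any simulation at most 8 unchanged genes were called. A 4-fold change in FPKM is under 4-fold on log2(FPKM + 1), so it lies below the threshold. At 4-fold, 19.0% of the changed genes were called for testis against brain (11066 genes). The share was 11.5% for testis against liver (9072 genes) and 11.0% for brain against liver (9602 genes).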

Results

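Polyadenylated RNA from the brain, liver and whole testis of male C57BL/6 mice aged 11 weeks was measured by strand-specific RNA sequencing, with 1 library per tissue. Gene abundances were the deposited FPKM values with their per-gene 95% intervals. Without replicates no difference between tissues could be set against the spread between animals, so differences are given by size and no p-values are reported. The intervals cover the estimation error within a library only. The fragments implied by those intervals came to 31.8 M in brain, 86.3 M in liver and 40.9 M in testis. Relative depth, read from genes with 1 fragment in both libraries, was 1.03 for testis over brain and 0.481 for testis over liver, so the implied fragments of brain and testis differed more than their depth. At 1 to 2 FPKM the median half-width of the interval was 16.4% of the value in brain, 11.4% in liver and 16.8% in testis, so the liver values were the most precise.

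The series title places the question in the complexity of the testis transcriptome, and the number and classes of genes detected in each organ were compared first. Long noncoding genes differed most in relative terms, with 806 of 3009 at 1 FPKM or more in testis, 251 in brain and 123 in liver. Protein-coding genes were about as many in testis as in brain, with 11673 and 11778 of 20147, while liver had 8837. Pseudogenes numbered 1849 in testis, 1584 in brain and 1476 in liver. Gene identifiers without a match in the reference numbered 1174, 859 and 520 in the same order. Small RNA genes were most numerous in brain, with 363, against 265 in testis and 211 in liver. Across all 36809 genes, 15778 reached 1 FPKM in testis, which was 42.9% (exact 95% binomial interval 42.4 to 43.4), 14845 in brain and 11170 in liver. Genes at this level in a single library numbered 3926 for testis, 2459 for brain and 840 for liver, and 9098 reached it in all 3 libraries. For protein-coding genes the order of testis and brain depended on the level. Testis had 15556 and brain 14950 at 0.1 FPKM, and testis had 5609 and brain 4909 at 10 FPKM. After scaling to the protein-coding FPKM sum, an alternative chosen after the data were examined, the order over all genes turned, with 15729 in brain and 15456 in testis. With the FPKM sum brain came below liver, with 5394 and 10433 genes, and testis had 13577.

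**Figure D1:**
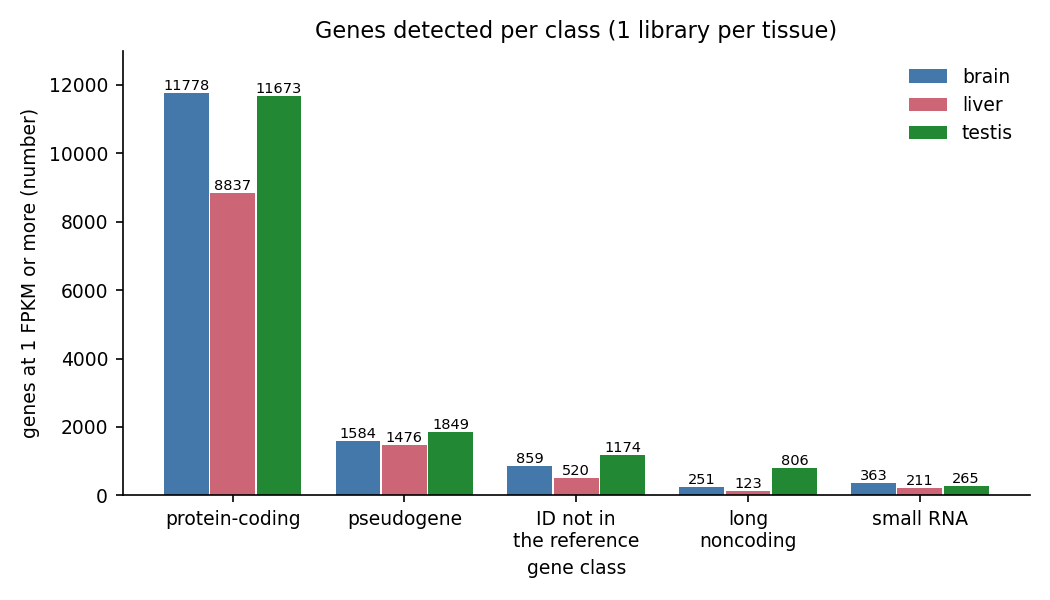
Number of genes at 1 FPKM or more (y axis) in each gene class (x axis) for the brain, liver and testis libraries, with 1 bar per library. Protein-coding genes numbered 11778 in brain and 11673 in testis, and long noncoding genes 806 in testis against 251 in brain.

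The most abundant protein-coding transcripts differed between the organs. In brain the 5 highest were mitochondrially encoded subunits of cytochrome oxidase, ATP synthase and NADH dehydrogenase, led by mt-Co2 at 21624 FPKM, mt-Atp8 at 7614 and mt-Co1 at 6479. In liver they were the plasma protein albumin (Alb, 20975 FPKM), mt-Co2 (17994), the major urinary protein genes Mup9 (17288) and Mup19 (16742), and transferrin (Trf, 17060). In testis they were the transition protein gene Tnp1 (14339 FPKM), the protamine gene Prm2 (12924), the germ cell lactate dehydrogenase gene Ldhc (6092), mt-Co2 (6026) and the spermiogenesis gene Meig1 (6004). Among protein-coding genes the 100 most abundant held 70.6% of the FPKM in liver, 35.1% in brain and 30.4% in testis. The 10 most abundant held 26.8%, 17.8% and 11.9%, and the Shannon entropy was 8.38, 10.90 and 11.09 bits in the same order. Mitochondrially encoded genes held 18.5% of protein-coding FPKM in brain, 10.1% in liver and 2.94% in testis.

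Over all genes the order was different, because features shorter than 200 bp took 96.0% of the FPKM in brain, 60.0% in testis and 30.6% in liver. The same features held 2.77%, 0.213% and 0.106% of the implied fragments. The 5 highest genes of the brain library were identifiers without a match, of 81 to 130 bp, led by ENSMUSG00000088174 on chromosome 16 (mm9, 57391659 to 57391739) at 1645450 FPKM. In testis the highest was Gm10180, a pseudogene of 78 bp on chromosome 9, at 224471 FPKM, followed by ENSMUSG00000088174, ENSMUSG00000088272, Mir682 and ENSMUSG00000089100. In liver the same Gm10180 was highest at 115694 FPKM, followed by Mup-ps17, Gm26377, Mir682 and ENSMUSG00000089681. With these features included, the 10 most abundant genes held 51.8% of the FPKM in brain, 30.5% in liver and 39.1% in testis. The 100 most abundant held 88.7%, 71.4% and 64.6%, with an entropy of 6.17, 8.20 and 8.49 bits.

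**Figure D2:**
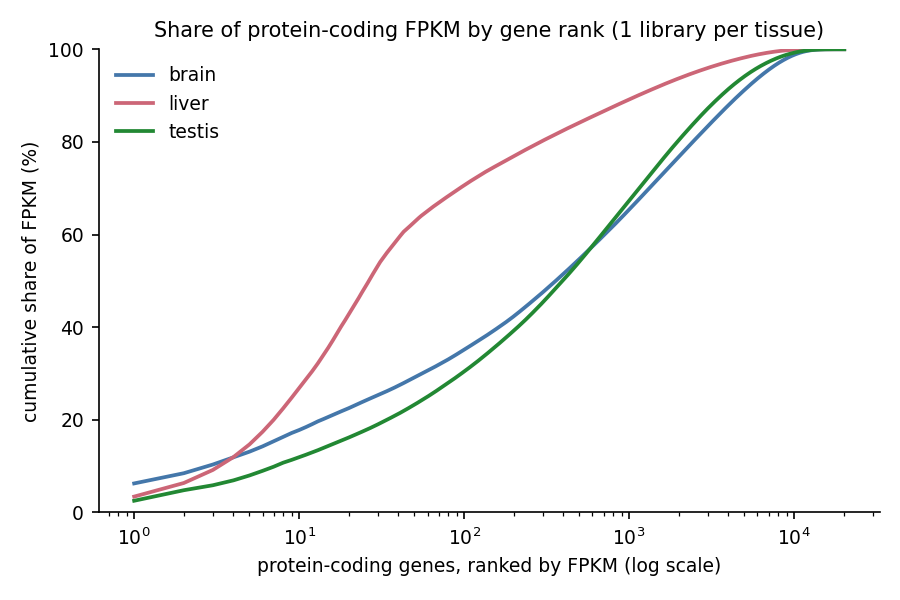
Cumulative share of protein-coding FPKM in percent (y axis) against gene rank on a log scale (x axis), with 1 line per library. The 100 most abundant genes held 70.6% in liver, 35.1% in brain and 30.4% in testis.

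Testis was then compared with brain. Among protein-coding genes the chemokine-like gene Cmtm2a led on the testis side, at 3287 FPKM against 0.194 in brain. Prm2, which packs sperm DNA, was at 12924 FPKM (interval 12884 to 12964) against 9.56, and Tnp2, a transition protein, at 4964 against 3.24. Ldhc was at 6092 against 4.64, and Smcp, a protein of the sperm mitochondrial capsule, at 2893 against 1.69. Brain held far more Snap25, which acts in synaptic vesicle fusion, at 933 FPKM (925 to 941) against 0.0864, and the myelin genes Mbp (869 against 0.583) and Mobp (601 against 0.411). The thyroid hormone carrier Ttr was at 1625 against 0.222. On the log2(FPKM + 1) scale these differences ran from 10.07 for Smcp to 11.43 for Cmtm2a, and from -8.74 for Mobp to -10.38 for Ttr.

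By the same size rule over all classes, genes annotated as short RNAs entered at the top. Mir147 at 28329 FPKM and the small nucleolar RNA gene Gm24339 at 8093 were listed at 0 in brain. The noncoding gene 4930570D08Rik (ENSMUSG00000084875, chromosome X, mm9 130433254 to 130435752) was at 1393 FPKM and was listed at 0 in both other libraries. In the other direction Mir1906-2, Snord47, Mir1906-1, Mir29b-2 and Gm25894, all of 75 to 81 bp, stood between 11725 and 18953 FPKM in brain and were listed at 0 in testis. For Gm24339 and Gm25894 the interval reached down to 0. A high FPKM in features this short need not mean many fragments. Features under 200 bp held 60.0% of the FPKM but 0.213% of the implied fragments in testis, and 96.0% but 2.77% in brain.

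Among all genes 4057 were at least 4-fold higher in testis than in brain with the intervals apart, and 2648 were at least 4-fold lower. Long noncoding genes were nearly all on the testis side, with 441 higher and 31 lower. Of the protein-coding genes 2862 were higher and 2094 lower, of the pseudogenes 327 and 107, and of the small RNA genes 10 and 128. The share of higher genes among those called was 60.5%. It depended on the scaling: 95.6% with each library scaled to its FPKM sum, 78.5% with the sum taken without the 100 most abundant genes, and 46.4% with the protein-coding sum.

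Testis was next compared with liver. Tnp1, which replaces histones in elongating spermatids, was at 14339 FPKM (14280 to 14398) against 0.0586, and Prm2 was at 12924 against 0.150. Ldhc, Tnp2 and Meig1 followed, at 6092, 4964 and 6004 FPKM in testis and 0.0211, 0.0360 and 0.368 in liver. Liver held far more of the major urinary proteins, pheromone carriers made by hepatocytes: Mup9 at 17288 FPKM (17192 to 17384) against 1.57, Mup11 at 16671 against 1.70, Mup19 at 16742 against 1.76, Mup18 at 15815 against 1.78 and Mup2 at 11630 against 1.10. The pseudogenes Mup-ps17 and Mup-ps19 were listed at 98789 and 12708 FPKM in liver. Mup genes are near-identical copies, and how reads were shared among them is uncertain, so the single values are less certain than their sum of 169066 FPKM over 18 genes, which was 27.6% of liver protein-coding FPKM.

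Counts against liver were higher on the testis side, with 5600 genes at least 4-fold higher in testis and 1405 lower. The split was 4060 and 1200 for protein-coding genes, 474 and 17 for long noncoding genes, 435 and 120 for pseudogenes, and 43 and 16 for small RNA genes. Higher genes made up 79.9% of those called, against 66.2% when the FPKM sum without the 100 most abundant genes set the scale. Over genes at 1 FPKM in any library, median-ratio scaling moved the median log2 difference by 0.01 for testis minus brain, -0.45 for testis minus liver and -0.43 for brain minus liver. The FPKM sum moved it by 1.16, -0.49 and -1.19 in the same order, the sum without the 100 most abundant genes by 0.78, -0.58 and -0.87, and the protein-coding sum by -0.49, 0.03 and 0.63.

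Brain against liver gave the difference between the somatic organs. Highest in brain among protein-coding genes were Cpe, a carboxypeptidase that processes neuropeptides, at 1160 FPKM (1154 to 1166) against 0.134, Snap25 at 933 against 0.0350, and the metallothionein Mt3 at 812 against 0.0372. The myelin genes Mbp and Mobp followed at 869 and 601 FPKM, against 0.173 and 0.00807. Highest in liver were Mup2 (11630 against 0.929), Mup9 (17288 against 2.67), the antitrypsin gene Serpina1e (15228 against 2.30), Alb (20975 against 3.73) and Mup19 (16742 against 3.22). Over all classes Mir1906-2, Snord47, Mir1906-1, Snord60 and Rny1 led on the brain side, at 11728 to 18953 FPKM, and each was listed at 0 in liver. Here too, such values in short features need not mean many fragments. In all, 3367 genes were at least 4-fold higher in brain and 1027 lower, with 2751 and 917 among protein-coding genes and 41 and 16 among long noncoding genes. The higher share of 76.6% became 64.8% with median-ratio scaling, 87.4% with the protein-coding sum, 37.2% with the sum without the 100 most abundant genes and 10.9% with the FPKM sum.

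Genes restricted to a single organ, at 5 FPKM or more in it and under 0.5 in both others, numbered 2037 for testis, 852 for brain and 368 for liver. With the FPKM sum they numbered 2071, 217 and 548, so that the order of brain and liver turned. As deposited, protein-coding genes made up 1230, 585 and 297 of them. Of the long noncoding genes at 5 FPKM or more in testis 74.8% were restricted to it, against 21.5% in brain and 22.0% in liver. The highest protein-coding ones in testis were Cmtm2a, Oaz3, an antizyme that restrains polyamine synthesis in spermatids, at 943 FPKM, the tubulin gene Tuba3a (737), Iqcf3 (693) and the glycolytic retrogene Pgk2 (686). Tnp1, Prm2 and Ldhc were higher in testis but stood at 13.5, 9.56 and 4.64 FPKM in brain, above the limit of 0.5. Carry-over from testis was not excluded for this brain signal, and its effect on the restricted genes was not tested. In brain the highest protein-coding ones included Snap25, Mobp, the calcium sensor Hpca (461) and the synaptic gene Cplx1 (398). In liver they were Serpina3k (4163, marked as a failed estimate with an interval that reached down to 0), the fibrinogen chain Fga (1888), the vitamin D binding protein gene Gc (1879), Ahsg (1867) and Mup5 (1730). Over all classes Mir147, Gm24339 and 4930570D08Rik entered the testis list, mt-Tl1 the liver list at 3920 FPKM (interval 0 to 11759), and short features alone filled the brain list, led by ENSMUSG00000075807 at 44960 FPKM. For the short features among them a high FPKM need not mean many fragments.

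Germ cell lists described the testis library by stage of spermatogenesis. Of 29 genes of spermatids and sperm 27 were at least 4-fold higher in testis than in brain, and 27 than in liver, with median log2 differences of 8.07 and 9.15. All 22 axoneme and flagellum genes were higher against both organs (5.28 and 6.59), led by Meig1, Ropn1l (2692 FPKM) and the radial spoke gene Rsph1 (1300). Of 25 genes of meiotic prophase 22 and 21 were higher (4.92 and 5.47), led by the synaptonemal complex genes Syce1 (587 FPKM) and Syce2 (227) and the chaperone gene Hspa2 (432) and Mns1 (319). Of 17 piRNA pathway genes, which silence transposons in germ cells, 15 and 16 were higher (4.18 and 4.38), led by Gtsf1 (1131), Mael (430) and Ddx4 (132). Testis histone and bromodomain genes gave 6 and 7 of 12 (2.19, or 1.89 with the protein-coding sum, and 2.88), with Hils1 at 413, H1fnt at 203 and Kdm3a at 66.3 FPKM.

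Spermatogonial genes went both ways. Against brain 4 of 15 were higher and 3 lower, with a median of -0.26 and a mean of 0.32, and against liver 6 were higher and 1 lower, with a median of 1.08. The liver-side median was 3.06 and 6.07 with pseudocounts of 0.1 and 0.01. Dmrtb1 was at 213 FPKM in testis, while Gfra1 was at 0.769 in testis against 7.42 in brain and 25.3 in liver. Uchl1 was at 25.5 FPKM in testis and 274 in brain, where it is a neuronal gene, Etv5 at 2.33 and 19.9, and Id4 at 11.2 and 13.6. The brain-side median turned to 0.44 with the FPKM sum and to 0.64 with the sum without the 100 most abundant genes.

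Lists of somatic genes of the testis were higher in part. Of 10 Leydig cell genes, which make androgens, 7 were higher in testis than in brain and 6 than in liver (4.14 and 3.98), led by Insl3 at 299 FPKM, marked as a failed estimate, the steroid hydroxylase gene Cyp17a1 at 76.6 and Fdx1 at 65.7. Of 16 Sertoli cell genes 7 and 8 were higher (1.79 and 2.49, but 2.17 and 1.72 with the FPKM sum), with Defb19 at 438 and Defb36 at 56.4 FPKM. Clu, on the same list, was at 750 FPKM in testis, 703 in brain and 1159 in liver. Apart from the spermatogonial list, the medians of these testis lists lay between percentiles 99.75 and 100 of matched random lists in both comparisons.

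Liver lists stood higher in liver throughout. Of 30 plasma protein genes 29 were at least 4-fold higher than in brain and 30 than in testis (median 9.46 and 9.11), led by Alb, Trf and the apolipoprotein Apoa1 (9952 FPKM). All 20 bile acid and xenobiotic genes were higher against both (6.34 and 5.87), with Cyp3a11 at 939, Cyp2e1 at 806 and Gsta3 at 645 FPKM. Of 20 genes of urea, amino acid and glucose metabolism 20 and 19 were higher (7.30 and 7.07), with Gnmt at 945 and Arg1 at 880 FPKM. The exception was Fbp1, an enzyme of gluconeogenesis, at 192 FPKM in testis and 223 in liver. Each of these medians lay at percentile 100.

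Neuronal and glial lists were higher in brain, each with a median at percentile 100 of matched random lists. All 18 general neuronal genes were higher in brain than in liver and 17 than in testis (6.97 and 6.75), led by Snap25, the synaptic vesicle gene Syp (316 FPKM) and Stmn3 (286). Excitatory synapse genes gave 14 and 13 of 16 (4.41 and 4.37), with Camk2a at 121, Camk2b at 104 and Slc17a7 at 100.2 FPKM. Inhibitory neuron genes gave 11 of 13 against both (5.63 and 5.61), with the neuropeptides Cck at 268 and Sst at 195 FPKM. Oligodendrocyte genes gave 15 and 14 of 15 (4.80 and 4.29), with Mbp and Mobp among the highest. Of 12 astrocyte genes 7 and 9 were higher (4.17 and 3.71), led by Glul (441), Aldoc (356) and Slc1a2 (148), while Aldh1l1 was at 222 FPKM in liver and 13.0 in brain. With the FPKM sum the medians of 3 of these lists came below 4-fold, at 1.29 and 1.28 for excitatory synapses, 1.13 and 0.89 for astrocytes and 1.47 and 1.29 for oligodendrocytes. General neuronal genes were then at 3.34 and 3.14 and inhibitory neuron genes at 2.15 and 2.14.

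Regional markers had smaller medians. Cerebellar genes gave 5 and 4 of 12 (1.83 and 1.54), with Itpr1 at 67.5 FPKM, Calb2 at 35.8 and Calb1 at 26.2, while the Purkinje cell gene Pcp2 was at 0.0496 and the granule cell gene Gabra6 at 0.0176. Choroid plexus genes gave 6 higher and 1 lower of 10 against liver and 3 higher against testis (2.18 and 1.58), with Ttr at 1625, Folr1 at 10.8 and Calml4 at 7.59 FPKM, and the water channel Aqp1 at 1.10 in brain and 7.99 in liver. None of 11 pituitary and hypothalamic peptide genes was 4-fold higher in brain (0.45 and 0.25, the second -0.02 with the FPKM sum). The medians were 1.96 and 1.87 among the members at 1 FPKM in any library. They were 2.23 and 1.10 with a pseudocount of 0.1, and 4.88 and 1.73 with 0.01. In brain Pmch was at 3.28, Crh at 2.88 and Pomc at 0.576 FPKM, and Pomc was at 6.18 in testis. At these brain levels the pseudocount of 1 leaves little room for a 4-fold call. The percentiles of these medians among matched random lists were 100 against both organs for the cerebellum, 99.89 and 99.35 for the choroid plexus and 99.85 and 98.2 for the peptides. With the FPKM sum the medians were 0.16 and 0.17 for the cerebellum and 0.28 and 0.02 for the choroid plexus. The choroid plexus median against liver also came below 4-fold with median-ratio scaling (1.92) and with the sum without the 100 most abundant genes (1.43).

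**Figure D3:**
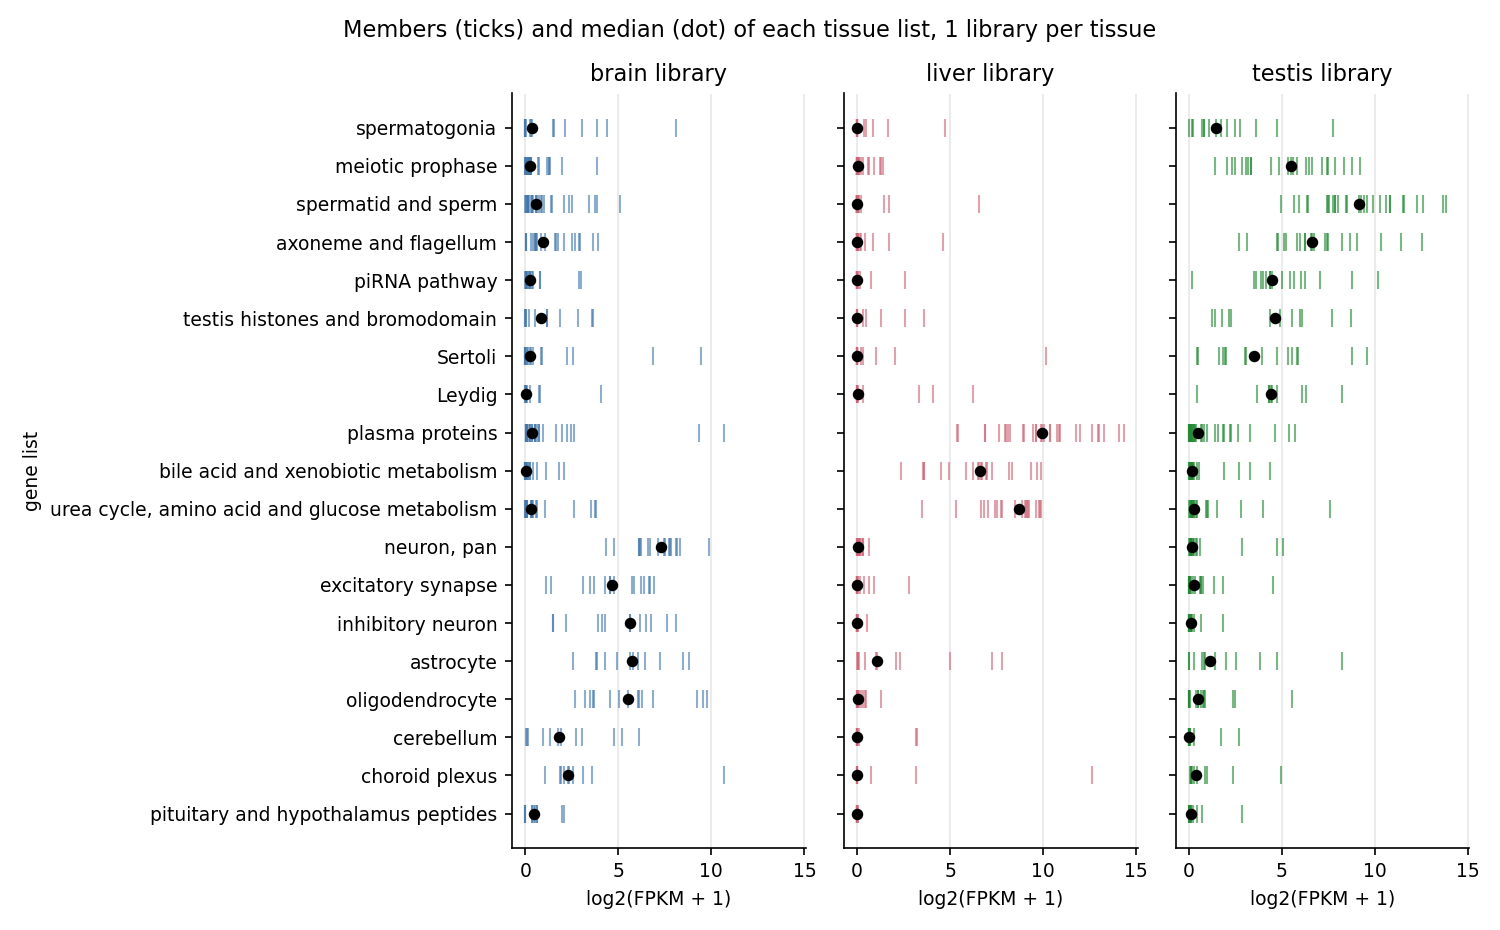
log2(FPKM + 1) on the x axis for the members (ticks) and the median (dot) of each tissue list (y axis), in 3 panels for the brain, liver and testis libraries. The spermatid and sperm list had a median difference of 8.07 to brain and 9.15 to liver, and the spermatogonial list -0.26 and 1.08.

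Lists of genes shared by the organs were compared in the 3 pairs of tissues. Endothelial genes had medians of -1.12 for testis minus brain, -0.85 for testis minus liver and 0.43 for brain minus liver, with 2 and 1 of 12 lower in testis and 1 higher in brain, but the first turned to 0.20 with the FPKM sum. The last turned to -1.05 with that sum, to -1.10 with the sum without the 100 most abundant genes and to -0.07 with median-ratio scaling. Cldn5 was at 20.02 FPKM in brain, Egfl7 at 9.38 and Flt1 at 7.68. Macrophage and microglia genes had medians of -1.79, -0.83 and 0.55, with 4 and 1 of 14 lower in testis, and 3 higher and 1 lower in brain than in liver, and the first turned to 0.10 with the FPKM sum. The last turned to -1.52, -1.19 and -0.12 under the same 3 scalings. C1qb was at 18.5 FPKM in brain and 6.07 in testis and Clec4f, a Kupffer cell gene, at 19.8 in liver, whereas Aif1 was at 375 in testis, 2.76 in brain and 2.16 in liver. Red blood cell genes had medians of -0.07 (mean -1.35), -1.22 and 0.07 (mean -0.20, and -0.89 with the FPKM sum). Among the members at 1 FPKM in any library the medians were -4.94, -3.44 and 1.501, with Hba-a1 at 152, 52.9 and 3.53 FPKM in brain, liver and testis, Hba-a2 at 124, 43.0 and 3.06, and Alas2 at 1.004, 41.2 and 6.91, estimates marked as failed in liver and testis. Smooth muscle genes had medians of 1.11, 1.36 and 0.16, the last turning to -0.61 with the FPKM sum, with Actg2 at 145 FPKM in testis, Myl9 at 25.6 and Acta2 at 22.3. Lymphocyte genes stayed low, with medians of -0.02 (mean 0.10, and 0.04 with the FPKM sum), -0.06 and -0.09 and Ptprc at 1.10 FPKM in liver. Among members at 1 FPKM in any library the last 2 were -0.86 and -0.70. Small medians of shared lists could also have extreme percentiles, such as 0.05 for lymphocyte genes in brain minus liver and 0.08 for endothelial genes in testis minus liver, so a percentile does not give the size of a difference. Epididymal genes had medians of 0.00, 0.01 and 0.00, and of 4.45, 4.60 and 0.15 among the members at 1 FPKM in any library. Of the 8 members Cst8 was at 227 FPKM in testis and Rnase10 at 1.67.

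Housekeeping genes had medians of -0.68 for testis minus brain, -0.18 for testis minus liver and 0.54 for brain minus liver, and the first turned to 2.05 and the last to -2.46 with the FPKM sum, and to 0.36 and -1.44 with the sum without the 100 most abundant genes. Median-ratio scaling turned the last to -0.16. Against brain 2 of 20 were at least 4-fold higher in testis and 4 lower, and against liver again 2 and 4. The elongation factor gene Eef1a1 was at 1891 FPKM in liver, and Ppia at 489 in brain. Tbp was at 130 FPKM in testis, 9.81 in brain and 6.01 in liver. Gapdh was at 10.5 in testis, 141 in brain and 57.1 in liver, and Hprt at 9.05, 118 and 41.3. Splicing regulators and RNA-binding proteins had medians of -0.25 (mean 0.12, and 0.78 with the FPKM sum), 0.92 and 1.83 (0.07 with the FPKM sum and 1.09 with the sum without the 100 most abundant genes), with 5 of 20 higher and 3 lower in testis than in brain. Against liver 9 of the 20 were higher and 1 lower in testis, and 8 higher and 1 lower in brain. Ybx2 was at 826 FPKM in testis, and Celf4 at 84.2 and Khdrbs3 at 64.5 in brain. DNA methylation and histone modifier genes had medians of 0.16, 1.12 and 0.77, the first turning to -0.51 with the protein-coding sum and the last to -0.66 with the FPKM sum, with 7 and 10 of 33 higher in testis and 4 in brain than in liver. Kdm3a was at 66.3, Ehmt2 at 58.8 and Kat8 at 57.9 FPKM in testis.

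The sex chromosomes are silenced during male meiosis, and X-linked genes were compared with autosomal genes. Among protein-coding genes at 1 FPKM or more the X to autosome ratio of median FPKM was 0.549 in testis, 0.974 in brain and 0.950 in liver. Over all genes it was 0.766, 0.963 and 1.08. This depended on the level: over all genes at 0.1 FPKM or more the ratios were 0.678, 0.680 and 0.685, so that testis did not stand apart, while among protein-coding genes they were 0.526, 0.772 and 0.708. Of 2573 X-linked genes 36.2% were detected in testis (exact 95% binomial interval 34.3 to 38.1), 25.5% in brain (23.9 to 27.3) and 17.8% in liver (16.4 to 19.4), against 43.5%, 41.8% and 31.5% of autosomal genes. X-linked genes made up 13.8% of the testis-restricted genes (12.3 to 15.4), 3.53% of the brain-restricted (2.39 to 5.0003) and 1.63% of the liver-restricted ones (0.602 to 3.52), and 7.07% of the annotated genes, counted over X and autosomes. Restricted to protein-coding genes the shares were 10.5%, 3.42% and 1.35%, against 4.15% annotated. The median log2 difference of protein-coding genes was -0.65 on the X and -0.02 on the autosomes for testis minus brain, but 1.26 and 1.08 for testis minus liver. These medians covered part of the genes, 604 on the X and 13676 on the autosomes against brain, and 516 and 12522 against liver. Of all 835 X-linked protein-coding genes 20.4% were at least 4-fold higher in testis than in brain and 17.1% lower. Of the 19270 autosomal ones 13.9% were higher and 10.1% lower.

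Of 9 Y-linked genes 3 were at least 4-fold higher and 0 lower in testis than in brain, and 3 higher and 1 lower than in liver. Between brain and liver 0 of the 9 were called. Eif2s3y, a translation factor gene, was at 16.9 FPKM in testis, 13.4 in brain and 14.2 in liver. Ddx3y was at 2.01, 10.03 and 12.8, Kdm5d at 0.322, 1.95 and 1.32, and Uty at 0.729, 1.795 and 1.97. Zfy1, Zfy2, Uba1y and Usp9y were at 3.15, 4.15, 3.83 and 0.472 FPKM in testis, and in brain and liver none of them passed 0.0557. Sry was at 0.0134 in testis and was listed at 0 in the other libraries. The list medians were 0.32 for testis minus brain, 0.23 for testis minus liver and 0.00 for brain minus liver.

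Autosomal retrogenes were compared with their X-linked parents in 11 pairs. The retrogene was above its parent in 10 of them in testis and in 0 of 11 in brain and in liver. The median log2 ratio in testis was 4.24. Rbmxl2 was listed at 0 in brain and in liver, and Cetn1 and Ubl4b in liver, so the medians of brain and liver, -3.51 and -2.44, are set by the pseudocount and are no folds. Pgk2 was at 686 FPKM in testis against 4.06 for Pgk1, which makes the same glycolytic enzyme in other cells, while brain had 0.475 and 108. The glycerol kinase pair Gk2 and Gk stood at 315 and 0.187 FPKM in testis, Cetn1 and Cetn2 at 602 and 18.1, the ribosomal pair Rpl10l and Rpl10 at 383 and 42.8, Ubl4b and Ubl4a at 114 and 2.89, and Pdha2 and Pdha1 at 50.5 and 1.73. G6pd2 was at 20.7 against 0.0243 for G6pdx, Rbmxl2 at 13.95 against 1.73 for Rbmx, Utp14b at 6.71 against 3.003 for Utp14a, and Zfa, a pseudogene in the reference, at 3.57 against 1.55 for Zfx. In the pair that went the other way, of a polyadenylation factor, Cstf2t was at 7.003 FPKM and Cstf2 at 67.6. Estimates of the parent were marked as failed for G6pdx in brain and liver and for Gk in liver, and the interval of Cstf2 in brain reached down to 0. In testis the intervals of Gk (0 to 1.08) and G6pdx (0 to 0.0540) did too, which leaves the size of their ratios open. Reads shared between a retrogene and its parent make single values uncertain.

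**Figure D4:**
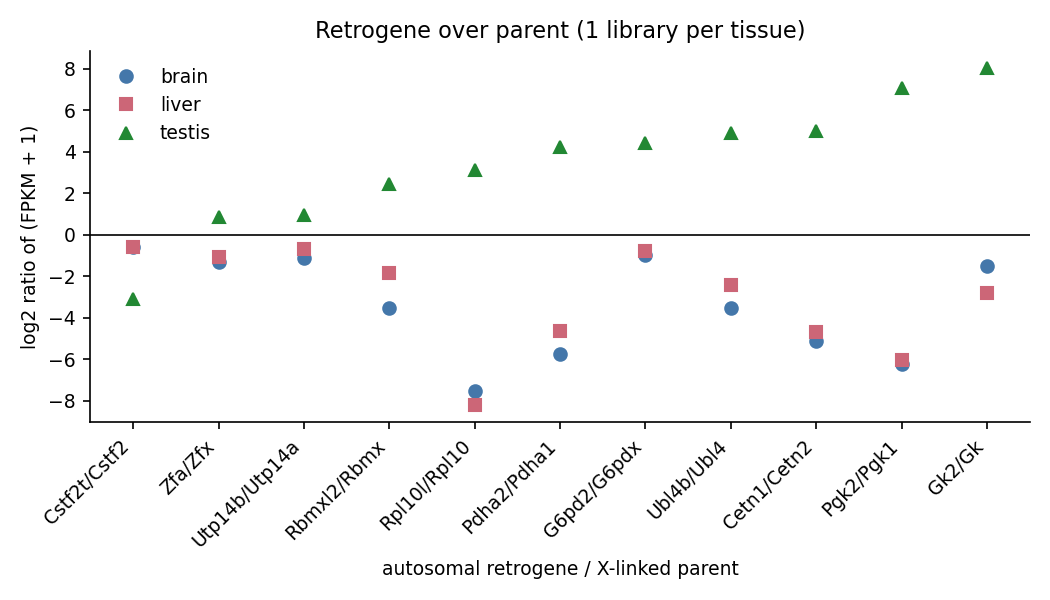
log2 ratio of (FPKM + 1), retrogene over parent (y axis), for 11 pairs (x axis) in the brain, liver and testis libraries, with 1 point per library. Testis points lay above 0 in 10 pairs and at -3.10 for Cstf2t over Cstf2, and the brain and liver points lay below 0 in all 11, where those of retrogenes listed at 0 are placed by the pseudocount.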

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

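Scaling to the protein-coding FPKM sum and the removal of features under 200 bp were chosen after the data were examined, and the other alternatives before. No paired analysis was possible because each tissue had 1 library, and for the same reason no library could be left out. Depth was lowest in brain and testis, where values at 1 to 2 FPKM carried a median half-width of 16.4% and 16.8%. No list median of at least 4-fold changed sign under the pseudocounts, scalings and filter run for lists. Retrogene ratios were run under other pseudocounts only, which cannot change their sign. Of the list medians, 92 values moved by more than the spread of the list's members and 384 did not, and of the single retrogene ratios 18 moved and 48 did not. Tissue list comparisons with a median at least 4-fold higher in the home tissue numbered 30, and 23 to 36 under the alternatives. The low of 23 came with the FPKM sum, where the excitatory synapse, astrocyte and oligodendrocyte medians against both organs, the choroid plexus median (0.28) and the Sertoli cell median (1.72) against liver came below 4-fold and the Sertoli cell median against brain (2.17) came above it. Median-ratio scaling and the sum without the 100 most abundant genes also took the choroid plexus median against liver below 4-fold (1.92 and 1.43), and the protein-coding sum that of testis histones against brain (1.89).

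Genes detected fell with the level by construction, to 9580 in brain, 6358 in liver and 10321 in testis at 5 FPKM, and to 6680, 4364 and 7742 at 10 FPKM. A lower bound above 0 gave 16772 in liver. With the FPKM sum the brain count was 5394, below the 10433 of liver, and that of restricted genes in brain 217, below the 548 of liver, so both orders turned. Protein-coding genes alone left 1230 genes restricted to testis.

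Concentration moved with the genes used. In brain the share of the 10 most abundant became 17.8% among protein-coding genes and 13.2% without features under 200 bp, that of the 100 most abundant 35.1% and 33.7%, and the entropy 10.90 and 11.08 bits. In testis the shares became 11.9% and 9.18%, and 30.4% and 26.2%.

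For testis against brain the genes higher in testis numbered 6910 with a pseudocount of 0.01, 6641 with the FPKM sum, 6486 at 2-fold and 2252 at 10-fold. The genes lower numbered 4296 and 5036 with pseudocounts of 0.1 and 0.01, 304 with the FPKM sum, 1510 with the sum without the 100 most abundant genes, 5131 at 2-fold and 1115 at 10-fold. With the protein-coding sum 3384 were higher and 3909 lower, so that the majority turned.

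For testis against liver the higher genes numbered 8748 and 10456 with pseudocounts of 0.1 and 0.01, 9032 at 2-fold and 2974 at 10-fold. The lower ones numbered 2152 and 2565 with the same pseudocounts, 2442 with the sum without the 100 most abundant genes, 2565 at 2-fold and 677 at 10-fold.

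For brain against liver the higher genes numbered 6139 and 7897 with pseudocounts of 0.1 and 0.01, 508 with the FPKM sum, 1710 with the sum without the 100 most abundant genes, 5398 with the protein-coding sum, 7117 at 2-fold and 1534 at 10-fold. The lower ones numbered 1854 with a pseudocount of 0.01, 4142 with the FPKM sum, 2883 with the sum without the 100 most abundant genes, 1786 at 2-fold and 577 at 10-fold. The FPKM sum and the sum without the 100 most abundant genes thus turned the majority. A smaller pseudocount raises the calls among low genes and a fold minimum sets them by construction. The FPKM sum multiplied brain values by 0.0710 and liver values by 0.751, which lowers brain against liver by construction. Features under 200 bp held 96.0% of that sum in brain and 30.6% in liver. For the other sums the cause was not tested.

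X-linked genes detected were 37.5% in brain, 28.0% in liver and 52.5% in testis at 0.1 FPKM, 15.9%, 10.1% and 21.8% at 5 FPKM, and 46.3%, 28.7% and 55.1% among protein-coding genes. The X to autosome ratio in liver was 0.685 at 0.1 FPKM. The median retrogene ratio with a pseudocount of 0.01 was -6.54 in brain and -8.03 in liver, against -3.51 and -2.44 with 1. Retrogenes listed at 0 enter these medians, so the pseudocount sets their size by construction and they are no folds.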

Other observations

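The genes and families of the next paragraph, and the tests of a constant share in brain and of effective length, were chosen only after the result was seen, as was scaling to the protein-coding sum, and the other tests before.

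Of the metabolic and translation genes examined, some testis forms stood above the general form in testis and others did not. Along glycolysis Gapdhs, the sperm form of the enzyme, was at 1254 FPKM in testis and Gapdh at 10.5, Pgam2 at 769 and Pgam1 at 14.5, and Ldhc at 6092 with Ldha at 229. In brain the same pairs stood at 0.653 and 141, 3.04 and 122, and 4.64 and 64.5. Among respiratory genes the testis cytochrome c gene Cyct was at 82.9 and Cycs at 8.12, Cox8c at 882 and Cox8a at 8.49, and Cox6b2 at 133 and Cox6b1 at 39.1. On the other side Aldoart1 was at 69.6 FPKM in testis, 77.3 in brain and 4.01 in liver, with Aldoa at 147, 527 and 24.7. Aldoart2 was at 129, 14.6 and 0.609 in the same order, and in testis Eno4 was at 22.6 with Eno1 at 238. Reads shared with Aldoa make the values of Aldoart1 and Aldoart2 uncertain, which was not tested. Among poly(A)-binding protein genes the general form Pabpc1 was at 996 FPKM, Pabpc2 at 394 and Pabpc6 at 95.7 in testis, against 57.1, 0.188 and 0.0788 in brain. By family, 28 of 39 kinesin genes were detected in testis, 18 in brain and 11 in liver, and 61 of 93 potassium channel genes in brain, 22 in testis and 3 in liver. Of 97 Cyp genes 60 were detected in liver and 16 each in brain and testis, and of 851 olfactory receptor genes 4 were detected in testis, 1 in brain and 1 in liver.

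Spermatid transcripts were listed at a low level in brain, with Prm2 at 9.56, Tnp1 at 13.5 and Ldhc at 4.64 FPKM, against 0.150, 0.0586 and 0.0211 in liver. Testis RNA or reads carried into the brain library at a constant share would give these genes a common ratio, and of 69 genes chosen without the brain values (testis at least 500 FPKM, liver under 0.5) 65.2% lay within 2-fold of the median ratio of 10.6 per 10000, between the 75% set as needed and the 50% set as excluding it. Of the others 7 lay below that window and 17 above it, and these counts, looked at only once that share had decided nothing, gave no value that excludes the explanation and are no second test of it. Carry-over and low transcription in brain therefore cannot be told apart, and no second brain library was analysed here. Ratios per 10000 were also read for list members at 50 FPKM or more in testis. The 27 of the spermatid list had a median of 6.92, with quartiles of 5.66 and 10.02. The 16 of the axoneme list, with genes of brain cilia, had a median of 69.4, with quartiles of 24.2 and 411. The spermatid ratios thus lay close together, as a constant share would give, and the axoneme ratios did not. Subtracting the median share would take 49 of 14845 genes from the brain count at 1 FPKM and 365 of 19676 at 0.1 FPKM.

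Features under 200 bp held 96.0% of the FPKM in brain. Division by a very small effective length may account for part of it: relative to single-transcript genes of 1 to 3 kb, a fragment in a feature under 100 bp was worth 2675 times the FPKM that the annotated lengths give in brain, 761 times in testis and 325 times in liver. These values rest on 136 such features in brain, 19 in testis and 26 in liver, so they do not compare the libraries on the same features. A larger share of fragments in features under 200 bp in the brain library also had the value it needs, at 13.0 times that of the next library. Both remain open together, and why brain had more fragments in features under 200 bp was not tested.

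More genes were detected in testis than in brain and liver at 1 FPKM. Deeper sequencing as the whole cause was argued against: thinned to 26.4 M implied fragments, testis had 1.09 times as many genes with 10 fragments as brain (17973 against 16543), and 13613 against 13335 among protein-coding genes. For a few genes taking most of the signal elsewhere, median-ratio scaling left a ratio of 1.06, the result set beforehand as arguing against it. Its factors were 0.878 for testis and 0.862 for brain, so it could hardly change their order and does not settle the question. With the protein-coding sum, examined later, brain had 15729 and testis 15456, so the order depends on the scaling. Among protein-coding genes testis was below brain at 1 FPKM (11673 against 11778) and above it at 0.1, 0.5, 5 and 10 FPKM, with 5609 against 4909 at 10. A difference between the tissues stays open and untested, with 1 library each.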
